A study of Mus musculus with 10 samples.

How the data were processed

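Poly(A) RNA of P14 CD8 T cells was sequenced in 10 libraries of 4 groups: Naive (n = 3), MPEC (n = 2), SLEC (n = 3) and Memory (n = 2). The mice were female C57BL/6 animals, per the labels. RNA was isolated with a column kit, poly(A) RNA was selected, and libraries were made with the NEBNext Ultra RNA kit, per the labels' protocols. That kit does not mark the strand. Reads of a gene and of an overlapping antisense gene are therefore not separated. Reads were processed by the authors with TopHat2 2.1.1, Cuffdiff and Cufflinks 2.2.2 on the mm10 build, per the submitters' processing notes. The annotation behind the gene symbols is not given in the sources used here.

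The deposited table gives 1 value per gene, group and replicate, per the file headers. Its fragments per gene are the authors' estimated counts, not normalized, and 97.3% of those above 0 were whole within 0.001. The authors' FPKM values, fragments scaled by transcript length and library size, are normalized per the file headers. Replicates are numbered from 0 in the table and from 1 in the labels, and index 0 was read as replicate 1. Of 24343 genes, 94 carried a status other than OK in at least 1 library and were left out: 70 with the status HIDATA and 24 with the status FAIL. HIDATA values were all exactly 0. Fragments ranged from 28954673 to 76927435 per library on all genes of the table and from 28213809 to 75611285 on the remaining 24249.

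Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, glmQLFit and glmQLFTest) in 1 fit of all 10 libraries with group as the only term. Of the 24249 genes, 13572 passed the filter. Benjamini-Hochberg adjustment ran over all genes tested within each of 6 comparisons, and a gene was called at an adjusted p below 0.05. Fold changes are from this fit on counts, with SE on the log2 scale, and levels are the authors' FPKM with SD. The SE is the absolute log2 fold change divided by the square root of the F statistic of the test. It was not estimated from the coefficient itself, and it need not cover the uncertainty where a group has few fragments. Where a group had 0 fragments, the fold was set against a floor of 3 fragments per library, and with 1 to 3 fragments a ratio is given with its 95% counting interval. Intervals and floors cover counting error only. With 2 libraries in MPEC and in Memory, all groups share 1 estimate of the spread.

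Before the data were examined, 26 gene lists were fixed, along with the tests, the alternatives and the rule for genes the text may name. The lists cover gate markers, cytotoxic effector molecules, effector-associated and naive- and memory-associated transcription factors, lymphoid homing and trafficking, peripheral migration receptors, cytokine receptors, inhibitory receptors and TOX, and NK-type receptors. Others cover the S phase, the G2/M phase, glycolysis, fatty acid oxidation, oxidative phosphorylation, survival and apoptosis, interferon-stimulated genes, chromatin modifiers, and immediate early and stress genes. The rest hold markers of B cells, myeloid cells, dendritic cells, CD4 T cells, NK cells, plasma cells, and red cells and platelets, and Y-linked genes. Some genes stand on several lists. Among them, the gate genes Klrg1 and Il7r stand on the NK-type receptor and cytokine receptor lists as well. Counts and camera results of those lists thus include a gene set by the sort. Ccr9 and Bst2, on the dendritic cell list, also stand among the lymphoid homing and the interferon-stimulated genes. Lists with at least 5 genes tested were compared with all other genes by camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01). Adjustment ran over 144 tests, and each call was repeated with an estimated correlation. Of 85 camera calls, 11 passed with an estimated correlation. These were cytotoxic molecules and effector-associated factors in each group against Naive, and NK-type receptors in SLEC and in Memory against Naive. The others were inhibitory receptors and TOX in Memory against Naive, and S phase genes in Memory against MPEC and against SLEC.

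The text may name the gate markers, 30 genes chosen in advance, the 4 members of each list with the smallest adjusted p in a comparison, and the 6 genes with the largest rise and the 6 with the largest fall. These last had to be called, to reach a mean of 5 FPKM in the higher group and to have FPKM ranges that do not overlap, and predicted genes, small RNA, histone, immunoglobulin and T cell receptor genes and merged entries were left out there. This rule covers 730 pairs of a gene and a comparison. Of these, 340 were chosen to be examined after their values were seen and before the alternatives were computed. Genes that stand in a described pattern outside the rule were chosen after their values were seen. Gene positions are from GENCODE M21 on mm10, which matched 23284 of 24249 symbols directly and 675 by an older symbol. Only the chromosome counts of the genes with the status HIDATA are from RefSeq. Globin genes, Klr family genes and MHC class II genes have near-identical copies, and their values are uncertain where the authors' counting could split reads between them. Overlapping gene models cover 68.7% of the exonic length of Itgam, 57.2% of that of Mzb1 and 25.9% of that of Ifng.

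Library pairs of 1 group differed by at least 5.87 times sampling noise (chi-square per degree of freedom), so none was taken for 1 library deposited as 2. This does not separate animals from repeat preparations of 1 sample, and each library was counted as a replicate because the series describes it as one. The fit was tested on simulated data with 200 changed genes. Genes were drawn independently of each other, each with 1 spread for all libraries. The shares recovered and false therefore do not cover groups that differ in spread. For SLEC vs MPEC, over 13271 genes, edgeR recovered 9.23% of genes changed 1.5-fold, 61.5% of those changed 2-fold and 78.5% of those changed 4-fold, with 3.96% of its calls false. In that simulation 20.7% of the calls of DESeq2 1.42.0 were false and 4.95% of those of limma over 11024 genes. This limma run used log2(CPM + 1) of the simulated counts, so its share does not cover the limma alternatives on FPKM. In the same simulation camera called 0 of 40 random lists and the list that had been changed. With independent genes, this could not show how camera treats lists whose members vary together. For Memory vs MPEC, over 13249 genes, edgeR recovered 4.76%, 37.9% and 78.8% at these folds with 3.61% of calls false. Of the calls in the simulations of MPEC vs Naive, SLEC vs Naive, Memory vs Naive and Memory vs SLEC, 4.30%, 8.04%, 6.00% and 8.51% were false.

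Alternatives were RLE and upper-quartile scaling, DESeq2, no count filter, a filter of at least 10 CPM in 2 or more samples, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean of at least 1 FPKM, a fit of only the groups compared, the replicate number as a block, leaving out each library in turn, and a log2 fold change of at least 1. Added after seeing the data were fits that keep the genes with a status other than OK, that leave out both MPEC libraries, or that leave out Memory replicate 2. The results of some genes are not reported here. Figures were drawn with matplotlib 3.10.9.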

Results

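Poly(A) RNA was profiled in P14 CD8 T cells, mouse T cells that carry a transgenic receptor for a peptide of lymphocytic choriomeningitis virus (LCMV). The 10 libraries fall into 4 groups. Naive cells (CD8+ CD44-) came from uninfected mice (n = 3). Memory precursor effector cells (MPEC, IL-7R high and KLRG1 low, n = 2) and short-lived effector cells (SLEC, IL-7R low and KLRG1 high, n = 3) were sorted as CD44+ Thy1.1+ cells on day 9 of an acute infection. Memory cells (n = 2) were taken with the MPEC gate on day 40 or later. Total fragments on genes were 54503898, 38271902 and 31096829 in the Naive libraries, 68134957 and 76927435 in MPEC, 47243558, 61288880 and 53249184 in SLEC, and 33538014 and 28954673 in Memory. The series describes the libraries as biological replicates and names no animals, so p-values measure the spread between these samples, pooled over all groups. Across genes, libraries of 1 group correlated at 0.992 or more in Naive and at 0.991 or more in SLEC, but at 0.951 in MPEC and 0.954 in Memory (Pearson's r of log2 CPM). The median SD of a gene within a group was 0.11 in Naive, 0.16 in SLEC, 0.27 in MPEC and 0.29 in Memory on the same scale. MPEC and Memory thus varied more than the groups they share the estimate of the spread with.

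**Figure D1:**
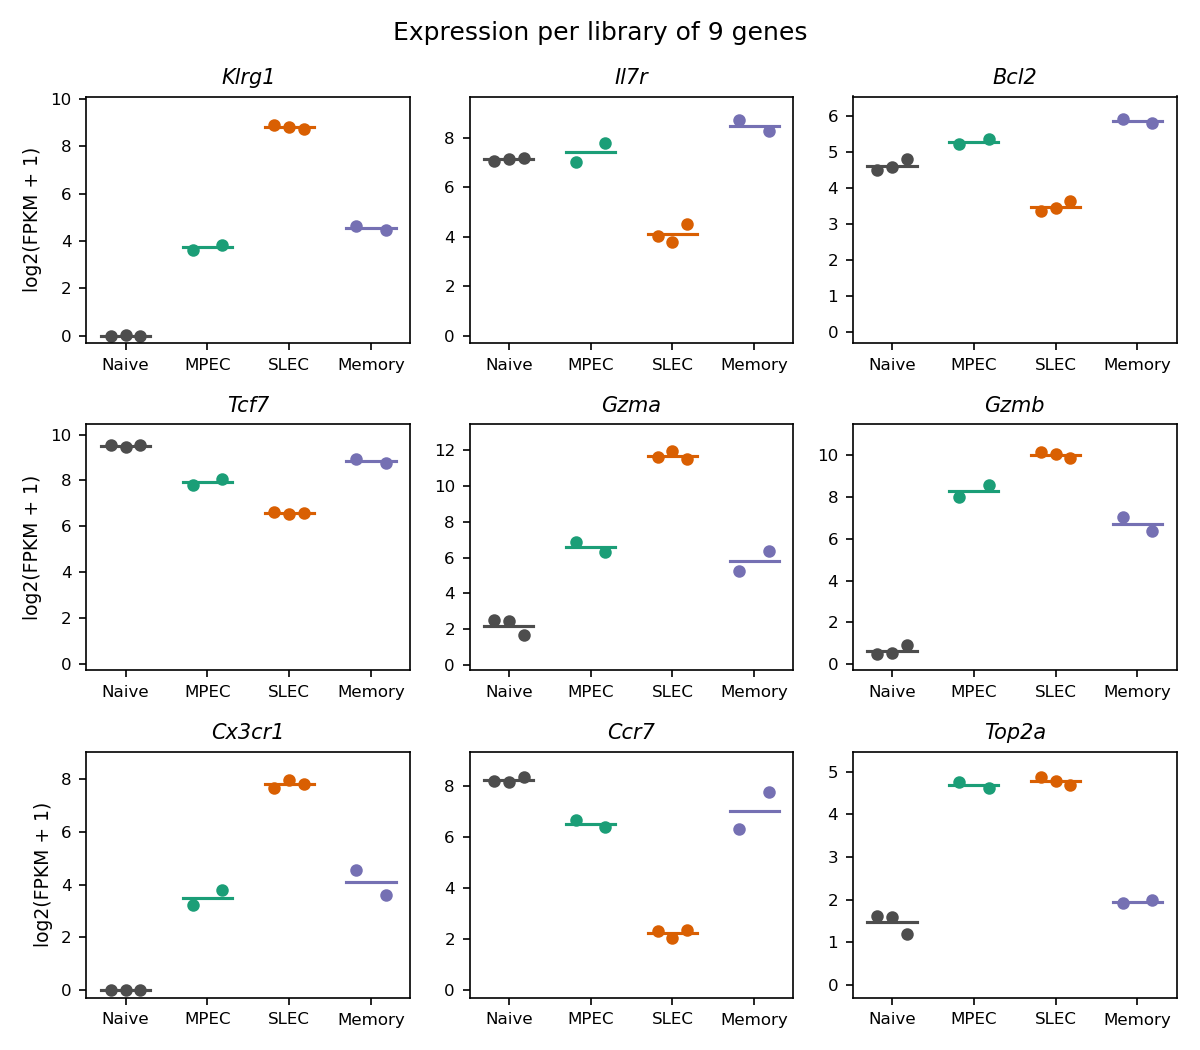
Expression of 9 genes in each library, as log2(FPKM + 1), by group; each point is 1 library and each line the mean of its group. Klrg1, Gzma, Gzmb and Cx3cr1 stood highest in SLEC, Tcf7 and Ccr7 stood highest in Naive, and Top2a stood highest in the day 9 groups.

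The comparison of SLEC with MPEC asks what separates effector subsets sorted on the same day by opposite IL-7R and KLRG1 gates. SLEC carried far more transcript of Gzma, a granzyme of cytotoxic granules, at 3316 ± 554 FPKM (SD, n = 3) against 97.1 ± 25.8 in MPEC (SD, n = 2), 35.6-fold higher. S1pr5 and Cx3cr1, receptors of circulating effector cells, were 39.9-fold and 22.2-fold higher in SLEC (S1pr5 61.4-fold without MPEC replicate 2), and the transcription factor Zeb2 was 9.03-fold higher. Ccr7, a receptor of lymph node homing, went the other way and was 23.2-fold lower in SLEC (3.75 ± 0.51 against 90.7 ± 11.8 FPKM). Klrg1 and Il7r, which the gates themselves set, were 38.3-fold higher and 10.2-fold lower. All of these changes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, from adjusted p = 1.18e-07 for Klrg1 to 8.92e-05 for Zeb2. On mm10, GENCODE places Gzma at chromosome 13, 113093825 to 113100981, S1pr5 at chromosome 9, 21242912 to 21248443, and Ccr7 at chromosome 11, 99144196 to 99155077, all protein-coding.

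Of 20 cytotoxic effector molecules, 10 rose and 1 fell in SLEC against MPEC (12 and 1 adjusted over the list alone). Gzmb rose by 1.78 ± 0.27 on the log2 scale (SE), Prf1, the pore-forming perforin, by 1.55 ± 0.25, and the chemokine Ccl3 by 2.19 ± 0.34, while Ifng stood at 443 ± 79.5 FPKM in SLEC and 408 ± 182 in MPEC and did not pass (edgeR adjusted p = 0.764). The list passed camera (adjusted p = 0.00517, adjusted p = 0.203 with an estimated correlation). Among 12 NK-type receptors, 7 rose and the others did not pass (8 adjusted over the list alone), with Klre1 at 5.83 ± 0.38 and Klrb1c at 1.90 ± 0.21 (camera adjusted p = 3.78e-05, adjusted p = 0.0584 with an estimated correlation). That list holds Klrg1, so its count and camera result include a member set by the gates. Of 17 peripheral migration receptors, 6 rose and 1 fell (7 and 3 adjusted over the list alone, camera adjusted p = 0.0314, adjusted p = 0.539 with an estimated correlation). The integrin gene Itgam rose by 2.42 ± 0.20, with 68.7% of its exonic length shared with an overlapping gene model. Lymphoid homing genes were lower for 5 of 10 (5 adjusted over the list alone, camera adjusted p = 0.00373, adjusted p = 0.273 with an estimated correlation). Cytokine receptors gave 1 higher and 5 lower of 18 (1 and 6 adjusted over the list alone, camera adjusted p = 0.0236, adjusted p = 0.482 with an estimated correlation), with Il18rap higher and Il6ra and Il4ra lower. The lower members include Il7r, which the gates set. Without MPEC replicate 1 cytotoxic molecules gave 7 higher and 2 lower (camera adjusted p = 0.0766) and peripheral migration receptors 3 higher (0.309). Peripheral migration receptors gave 3 higher without SLEC replicate 2 (0.0262) and 5 without SLEC replicate 3 (0.0501), and without MPEC replicate 2 homing genes gave 3 lower (0.0696) and cytokine receptors 2 higher and 3 lower (0.525).

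Neither list of transcription factors passed camera in SLEC against MPEC. Tbx21, which encodes T-bet, rose by 1.23 ± 0.22 and Prdm1, which encodes Blimp-1, by 1.70 ± 0.32, among 5 effector-associated factors higher and 2 lower of 14 (5 and 3 adjusted over the list alone, camera adjusted p = 0.349). Tcf7, which encodes TCF-1, fell by 1.31 ± 0.13, Id3 by 2.46 ± 0.44, Myb by 2.66 ± 0.43 and Bach2 by 1.11 ± 0.18. These are among 7 naive- and memory-associated factors lower and 1 higher of 16 (7 lower and 4 higher adjusted over the list alone, camera adjusted p = 0.122). Lef1 was close in both, at 56.5 ± 2.0 and 60.5 ± 3.3 FPKM (edgeR adjusted p = 0.910). Bcl2, a survival gene, fell by 1.87 ± 0.16, among 3 higher and 1 lower of 16 survival and apoptosis genes (3 and 1 adjusted over the list alone, camera adjusted p = 0.565). Of 20 S phase and 20 G2/M genes 0 passed in edgeR and 0 in DESeq2, with 4 and 1 at an unadjusted p under 0.05 in edgeR, and Top2a stood at 26.6 ± 1.8 against 24.9 ± 1.9 FPKM (edgeR adjusted p = 0.570). Interferon-stimulated genes were lower in SLEC for 10 of 20 and higher for 1 (13 and 1 adjusted over the list alone, camera adjusted p = 0.000436, adjusted p = 0.0584 with an estimated correlation), with Rsad2 at -1.72 ± 0.19 and Oasl2 at -1.98 ± 0.23. Beside these, 9 of 13 B cell markers were lower in SLEC (12 adjusted over the list alone, camera adjusted p = 1.10e-05, adjusted p = 0.285 with an estimated correlation). Myeloid markers were lower for 7 of 14 (11 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.00360, adjusted p = 0.1999 with an estimated correlation). Dendritic cell markers were lower for 3 of 8 (4 adjusted over the list alone, camera adjusted p = 0.00297, adjusted p = 0.0670 with an estimated correlation). Red cell and platelet markers were lower for 4 of 8 (5 adjusted over the list alone, camera adjusted p = 0.0452, adjusted p = 0.438 with an estimated correlation). Of 15 immediate early and stress genes 2 were lower (2 adjusted over the list alone, camera adjusted p = 0.946). Cd74, the invariant chain of MHC class II, stood at 193 ± 12.5 FPKM in SLEC and 731 ± 7.6 in MPEC. The B cell count was 4 without MPEC replicate 2 and 5 without SLEC replicate 1 or 2. The myeloid count was 4, 3 and 3 without SLEC replicate 1, 2 and 3. Dendritic cell markers gave 1 lower without SLEC replicate 1 or 2, and they lost all 3 calls without SLEC replicate 3. Red cell and platelet markers gave 1 lower and did not pass camera without MPEC replicate 1 (0.263) or SLEC replicate 1 (0.0545), 2 (0.0539) or 3 (0.0781). The 3 higher survival genes were 1 without SLEC replicate 2. Without MPEC replicate 1, or any 1 SLEC library, Irf4 and Irf8, the 2 lower effector-associated factors, and Egr2, 1 of the 2 lower immediate early genes, were not called. Irf8 was not called without MPEC replicate 2 either.

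In edgeR, 1448 of 13572 genes were higher and 1335 lower in SLEC than in MPEC, 52.0% of the calls higher, with 422 higher and 824 lower at a log2 fold change of at least 1. The share was 37.0% with upper-quartile scaling, which moved the median of all genes from 0.0011 to -0.10. The count of 2783 fell to 1419, 1364 and 1669 without SLEC replicate 1, 2 and 3. Leaving out 1 library ended the call of 9 of 56 genes examined, which with all libraries stood at 0.97 for Id2, -0.63 for Cd27, -1.15 for Cxcr3, -0.65 for Cd44, 4.92 for Cma1, -2.48 for Ctla4, -1.84 for Fosb, -5.34 for Gdf15 and -2.03 for Hbb-b1. Without SLEC replicate 1 the values were 0.96 for Id2, -0.63 for Cd27, -1.17 for Cxcr3, -0.69 for Cd44, 4.89 for Cma1, -2.66 for Ctla4 and -1.83 for Hbb-b1. Without SLEC replicate 2 they were 0.98 for Id2, -1.13 for Cxcr3, -0.56 for Cd44, 4.88 for Cma1, -2.24 for Ctla4 and -1.58 for Fosb, and without SLEC replicate 3 they were 0.95 for Id2, -0.62 for Cd27, -1.15 for Cxcr3, -0.74 for Cd44, 4.92 for Cma1, -2.59 for Ctla4, -1.88 for Fosb and -2.01 for Hbb-b1. Without MPEC replicate 1 they were 0.70 for Id2, -1.65 for Fosb and -2.74 for Gdf15, and without MPEC replicate 2 they were -0.32 for Cd27, -0.74 for Cxcr3 and -0.51 for Cd44. Gdf15 stood at -6.22 without MPEC replicate 2 and -5.98 without SLEC replicate 1, and Cma1, with 26 fragments in MPEC replicate 1 and 0 in MPEC replicate 2, at 3.89 without the latter.

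The comparison of Memory with MPEC sets the same gate on day 40 or later against day 9. Memory cells carried far less transcript of cell cycle genes: Top2a fell from 24.9 ± 1.9 FPKM in MPEC (SD, n = 2) to 2.88 ± 0.12 in Memory (SD, n = 2), 8.20-fold lower, Mki67 was 11.2-fold lower, and Rrm2, a subunit of ribonucleotide reductase, 7.79-fold lower. Of 12 inhibitory receptors and TOX, 1 was higher and 4 were lower (1 and 5 adjusted over the list alone, camera adjusted p = 0.140). Lag3 fell by 2.85 ± 0.26, Tigit by 2.64 ± 0.25 and Pdcd1, which encodes PD-1, by 2.13 ± 0.27 on the log2 scale (SE). Tcf7 rose 1.99-fold. The granzyme Gzmb fell by 1.49 ± 0.28. These changes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, from adjusted p = 1.42e-05 for Top2a to 0.00457 for Gzmb.

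Of 20 G2/M genes 19 fell (20 of 20 adjusted over the list alone, camera adjusted p = 6.44e-15, adjusted p = 0.140 with an estimated correlation), and 10 of 20 S phase genes fell (14 adjusted over the list alone, camera adjusted p = 3.00e-08, adjusted p = 0.04998 with an estimated correlation). Cdk1 stood at -2.99 ± 0.27 and Cdc6 at -3.41 ± 0.33. Effector-associated transcription factors gave 7 lower and 1 higher of 14 (8 and 2 adjusted over the list alone, camera adjusted p = 0.00923, adjusted p = 0.154 with an estimated correlation), led by Irf8 at -1.89 ± 0.16, Irf4 at -2.85 ± 0.49 and Bhlhe40 at -2.30 ± 0.49. Irf4 stood at -2.26 without Memory replicate 1 and -3.84 without Memory replicate 2. B cell and myeloid markers fell in this contrast too, and whether Irf8 and Irf4 fell in the T cells themselves was not tested. Tbx21 and Zeb2 were not called, at -0.10 ± 0.23 and -0.11 ± 0.29. Naive- and memory-associated factors were higher for 5 of 16 (5 adjusted over the list alone, camera adjusted p = 0.0235, adjusted p = 0.129 with an estimated correlation). Without Memory replicate 2, which held 10.9 FPKM of the Naive gene Itgae against 0.416 in Memory replicate 1, these gave 3 higher and 2 lower (camera adjusted p = 0.0718), with Lef1, Bach2 and Foxp1 no longer called, and without MPEC replicate 1 they gave 1 higher (0.0440). Effector-associated factors did not pass camera without Memory replicate 2 (0.0730) or MPEC replicate 2 (0.0550). Cytotoxic molecules gave 3 higher and 4 lower of 20 (3 and 4 adjusted over the list alone, camera adjusted p = 0.529), or 1 and 4 without MPEC replicate 1 and 4 and 2 without MPEC replicate 2. Inhibitory receptors and TOX gave 2 higher and 7 lower without Memory replicate 2. Interferon-stimulated genes were lower for 8 of 20 (10 adjusted over the list alone, camera adjusted p = 0.000149, adjusted p = 0.0584 with an estimated correlation), with Rsad2 at -2.09 ± 0.22 and Isg15 at -1.35 ± 0.20. The potassium channel gene Kcnj8 rose by 3.62 ± 0.32, Prss12 by 3.48 ± 0.25 and Il6ra by 2.25 ± 0.30. The glycolytic enzyme gene Hk2 fell by 1.97 ± 0.20, among 3 of 17 glycolysis genes lower (3 adjusted over the list alone, camera adjusted p = 0.195).

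Markers of other cell types moved with the same contrast: 10 of 13 B cell and 10 of 14 myeloid markers were lower in Memory than in MPEC (13 and 13 adjusted over the lists alone), with camera adjusted p = 7.81e-09 and 1.33e-07 (adjusted p = 0.187 and adjusted p = 0.0584 with an estimated correlation). Cd74 stood at 70.3 ± 23.6 FPKM in Memory and 731 ± 7.6 in MPEC, and Hbb-b1, a globin gene with near-identical copies, at 6.999 ± 6.705 and 787 ± 4.5. S100a8, a gene of neutrophils, had 1 fragment in Memory and 3303 in MPEC, a ratio of 1341 (95% counting interval 241 to 52993), and Ngp was at least 355-fold lower, against a floor of 3 fragments per library. Dendritic cell markers were lower for 4 of 8 (5 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.00106, adjusted p = 0.0584 with an estimated correlation). They share Ccr9 with the lymphoid homing list and Bst2 with the interferon-stimulated list. Red cell and platelet markers were lower for 5 of 8 (6 adjusted over the list alone, camera adjusted p = 5.35e-05, adjusted p = 0.158 with an estimated correlation). All 4 plasma cell markers tested were lower (4 adjusted over the list alone), or 2 without MPEC replicate 1 or Memory replicate 1. Immediate early and stress genes were lower for 5 of 15 (5 adjusted over the list alone, camera adjusted p = 0.0122, adjusted p = 0.539 with an estimated correlation). Atf3 and Nr4a1 were at -4.24 ± 0.83 and -3.26 ± 0.86, at -3.25 and -2.38 without Memory replicate 1, and at -8.05 and -5.84 without Memory replicate 2. That list gave 3 lower without MPEC replicate 1, and its camera adjusted p was 0.0957 without MPEC replicate 2 and 0.298 without Memory replicate 1.

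In all, 1122 genes were higher and 1183 lower in Memory than in MPEC, 48.7% of the calls higher, or 38.2% with RLE scaling, and 504 were higher and 923 lower at a log2 fold change of at least 1. With only these 4 libraries in the fit 494 were called, 67 higher and 427 lower, and Tcf7 (0.96), Klrg1 (0.91), Il7r (1.09) and Bcl2 (0.71) did not pass. Without MPEC replicate 2, 3483 were called, 1814 higher and 1669 lower. Leaving out 1 library ended or turned the call of 11 of 60 genes examined. Without Memory replicate 2 the integrin gene Itgae stood at -0.24 in place of 3.54, Fosb, still called, at -3.18 in place of -1.99, Lef1 at 0.18 in place of 0.74, Il6st at 0.53 in place of 1.05, Bach2 at 0.39 in place of 0.66, Gzmm at 0.62 in place of 0.78 and Foxp1 at 0.61 in place of 0.85. With all libraries Il7r stood at 1.12, Eomes at 1.14, Jchain at -1.18, Fosb at -1.99 and Bcl2 at 0.75. Without MPEC replicate 1 the values were 0.74 for Il7r, 1.04 for Eomes, 3.55 for Itgae, 0.48 for Bach2, 0.76 for Lef1, 0.81 for Il6st, -0.83 for Jchain, 0.60 for Foxp1, -1.80 for Fosb and 0.63 for Bcl2. Without MPEC replicate 2 they were 3.49 for Itgae, 0.70 for Lef1 and 0.55 for Gzmm, and without Memory replicate 1 they were 4.50 for Itgae, still called, 0.88 for Il7r, -0.91 for Jchain, -1.35 for Fosb and 0.56 for Bcl2. Ccr9, at 3.09 and not called, turned and passed at -1.29 without Memory replicate 2, and passed at 4.06 without Memory replicate 1. Not called with all libraries in the fit but passing with 1 left out were Ifng (-1.48 in place of -0.80), Gzma (-1.35 in place of -0.65), Tox (-0.75 in place of -0.26) and Prf1 (0.94 in place of 0.62) without Memory replicate 2, Ccr7 (1.30 in place of 0.75) without Memory replicate 1, and Prf1 (0.97) without MPEC replicate 2.

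**Figure D2:**
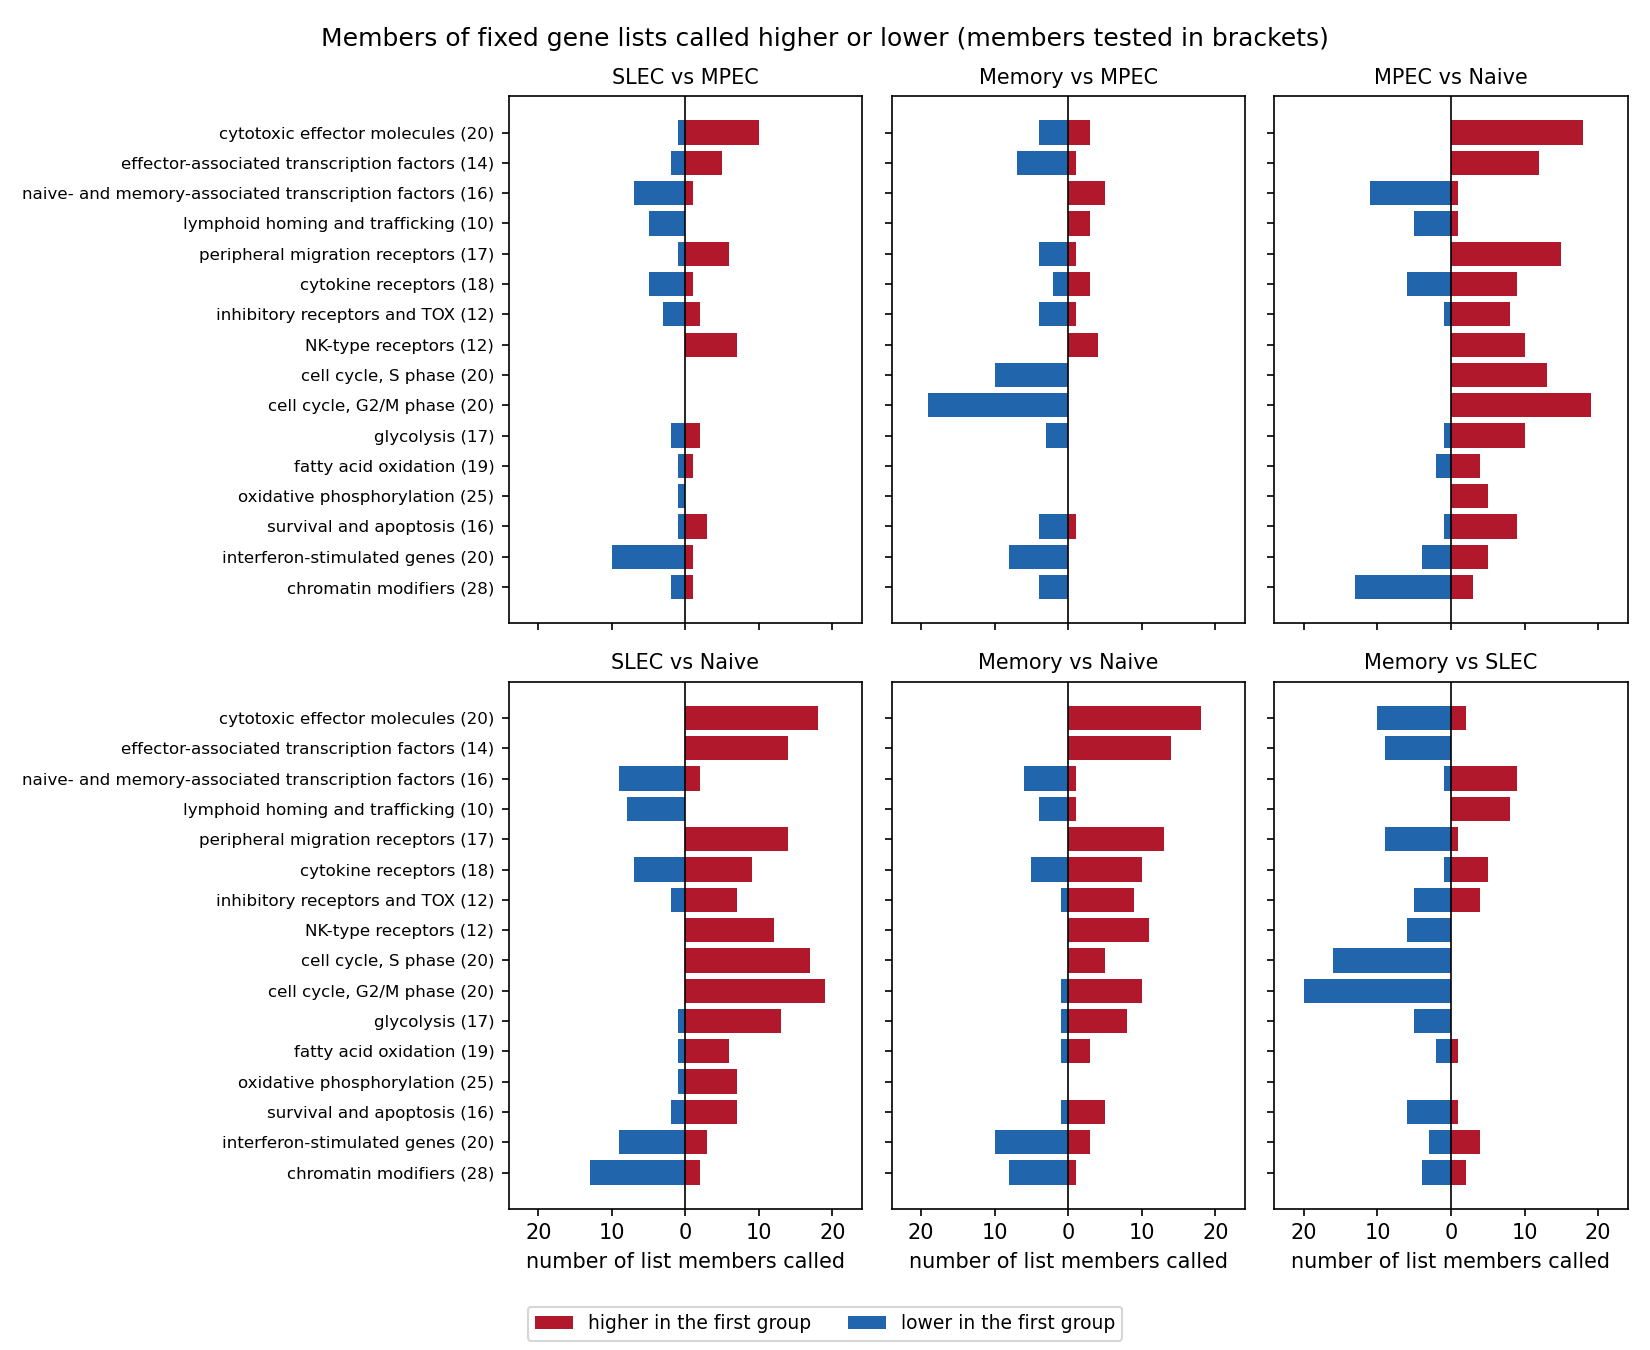
Number of members of 16 fixed gene lists called higher (red, right) or lower (blue, left) in the first group named, for 6 comparisons; the members tested stand in brackets after each list. In Memory vs MPEC 19 of 20 G2/M genes were lower and in Memory vs SLEC 20 of 20.

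The comparison of MPEC with Naive cells sets the precursor gate of infected mice against naive cells from uninfected mice. Antigen experience, infection of the mice and the sort differ together between these groups. The changes therefore cannot be assigned to antigen experience alone. MPEC carried more transcript of cytotoxic effector genes: the chemokine gene Ccl5 stood at 6210 ± 247 FPKM (SD, n = 2) against 7.31 ± 0.53 in Naive (SD, n = 3), 818-fold higher, Gzmb was 545-fold higher and Ifng 954-fold higher, or 1497-fold without Naive replicate 3. Gzmk had 0 fragments in Naive and was at least 640-fold higher, against a floor of 3 fragments per library. Cd44, the activation marker of the gate, was 29.2-fold higher, while Il7r did not pass (177 ± 66.7 against 139.5 ± 6.7 FPKM, adjusted p = 0.383). Tbx21 was 46.7-fold higher and Tcf7 3.10-fold lower, at 245 ± 31.5 against 732 ± 19.6 FPKM. Calls are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with adjusted p = 9.99e-11 for Ccl5 and 3.84e-06 for Tcf7.

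Of 20 cytotoxic molecules, 18 rose in MPEC against Naive (18 adjusted over the list alone, camera adjusted p = 1.71e-10, adjusted p = 0.04998 with an estimated correlation). Effector-associated factors were higher for 12 of 14 (12 adjusted over the list alone, camera adjusted p = 3.09e-08, adjusted p = 0.0495 with an estimated correlation). Naive- and memory-associated factors gave 11 lower and 1 higher of 16 (11 and 1 adjusted over the list alone, camera adjusted p = 0.00213, adjusted p = 0.0584 with an estimated correlation), with Lef1 at -1.90 ± 0.22, Foxo1 at -1.19 ± 0.14 and Id3 at -2.67 ± 0.46. Peripheral migration receptors were higher for 15 of 17 (16 adjusted over the list alone, camera adjusted p = 5.36e-09, adjusted p = 0.1496 with an estimated correlation), with Itgax at 12.04 ± 0.31. Inhibitory receptors and TOX gave 8 higher and 1 lower of 12 (8 and 1 adjusted over the list alone, camera adjusted p = 0.00214, adjusted p = 0.0584 with an estimated correlation): Lag3, Tigit and Pdcd1 rose, and Tox fell by 1.32 ± 0.24. Of 20 G2/M genes 19 rose (19 adjusted over the list alone, camera adjusted p = 2.03e-10, adjusted p = 0.198 with an estimated correlation), Mki67 by 5.37 ± 0.32. Glycolysis genes gave 10 higher and 1 lower of 17 (10 and 1 adjusted over the list alone, camera adjusted p = 0.0121, adjusted p = 0.381 with an estimated correlation), with Hk2 at 5.05 ± 0.20 and the glucose transporter gene Slc2a1 at 1.54 ± 0.15. Genes of fatty acid oxidation gave 4 higher and 2 lower of 19 (4 and 2 adjusted over the list alone, camera adjusted p = 0.595) and of oxidative phosphorylation 5 higher of 25 (1 adjusted over the list alone, camera adjusted p = 0.352). Among 28 chromatin modifiers 3 rose and 13 fell (3 and 14 adjusted over the list alone, camera adjusted p = 0.0199, adjusted p = 0.187 with an estimated correlation), with Ezh2, the Polycomb methyltransferase, at 1.21 ± 0.14. The cytokine receptor genes Il6ra and Il6st stood at -4.14 ± 0.31 and -3.39 ± 0.25. Without MPEC replicate 1 glycolysis genes gave 6 higher (camera adjusted p = 0.0455) and chromatin modifiers 8 lower, and without MPEC replicate 2 oxidative phosphorylation genes gave 10 higher (camera adjusted p = 0.0308). Oxidative phosphorylation genes gave 1 higher without MPEC replicate 1 or Naive replicate 3 and 2 without Naive replicate 1 or 2. Myb, the 1 higher naive- and memory-associated factor, was at an adjusted p of 0.0495 in edgeR and lost its call whichever of the 5 libraries was left out.

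Beside these, all 13 B cell markers and all 14 tested myeloid markers were higher in MPEC than in Naive (13 and 14 adjusted over the lists alone), with camera adjusted p = 7.81e-09 and 3.39e-09, and adjusted p = 0.187 and adjusted p = 0.0584 with an estimated correlation. NK cell markers were higher for 4 of 6 (4 adjusted over the list alone, camera adjusted p = 0.0187, adjusted p = 0.129 with an estimated correlation). Immediate early and stress genes were higher for 10 of 15 (10 adjusted over the list alone, camera adjusted p = 0.00618, adjusted p = 0.508 with an estimated correlation). Cd74 stood at 731 ± 7.6 FPKM in MPEC and 6.34 ± 1.35 in Naive, S100a8 at 116 ± 5.9 and 0.26 ± 0.27, and Hbb-b1 at 787 ± 4.5 and 2.18 ± 1.43. In all, 3194 genes were higher and 2793 lower in MPEC. Of 58 genes examined, leaving out 1 library ended the call of 1, Prf1, which stood at 0.99 and at 0.63 without MPEC replicate 2. With at least 10 CPM required in 2 or more samples, which left 8899 genes, 3802 were called in place of 5987.

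**Figure D3:**
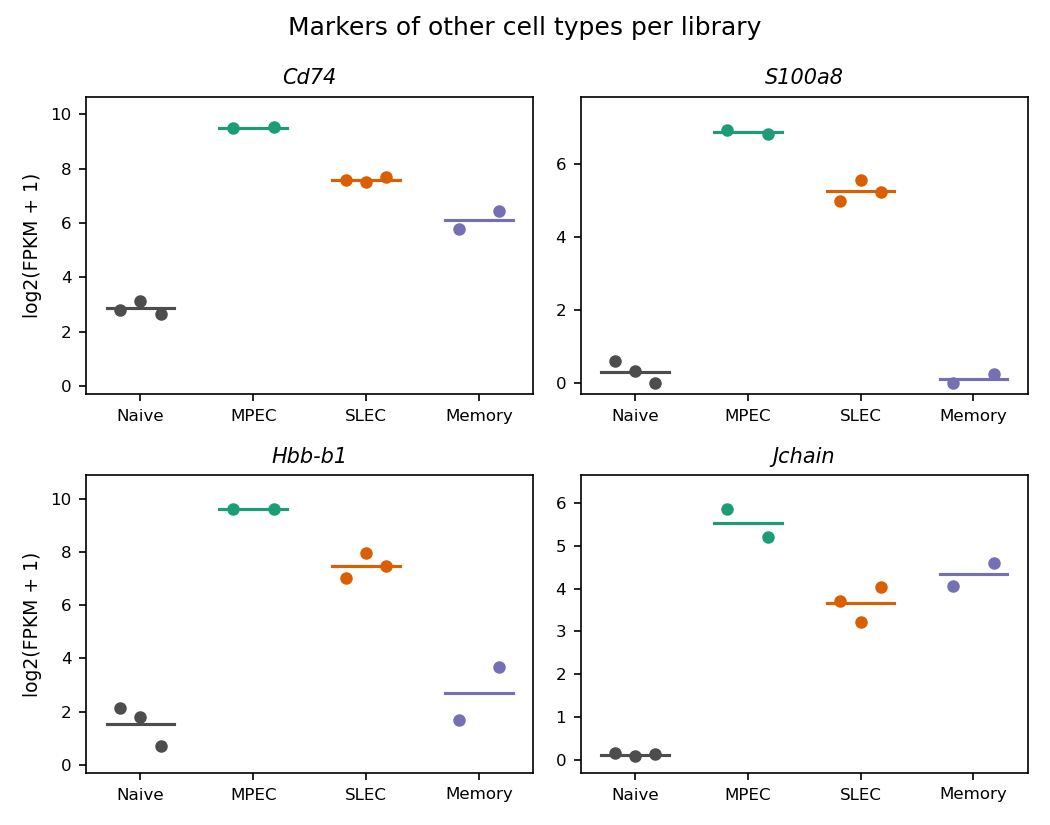
Expression in each library of 4 genes of other cell types, as log2(FPKM + 1), by group; each point is 1 library and each line the mean of its group. All 4 stood highest in the MPEC libraries, with Cd74 at 725 and 736 FPKM there.

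The comparison of SLEC with Naive cells gave the most calls. Klrg1 rose from 1 fragment in 3 Naive libraries to 454 ± 27.7 FPKM in SLEC (SD, n = 3), a ratio of 69950 (95% counting interval 12554 to 2762900). Ccl5 was 2473-fold higher, at 18017 ± 1593 FPKM, Gzmb 1878-fold higher, Gzma 871-fold higher and Fasl, a death ligand, 2488-fold higher. Fasl had 8 fragments in Naive, 7 of them in Naive replicate 3. It stood 1410-fold higher without Naive replicate 1 and 12767-fold higher without Naive replicate 3, against 1 fragment. Ccr7 was 78.3-fold lower, Tcf7 7.67-fold and Id3, a naive-associated factor, 35.0-fold lower. Bcl2 was 2.43-fold lower. The adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment ran from 3.42e-11 for Ccl5 to 2.50e-05 for Bcl2.

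All 14 effector-associated factors rose in SLEC against Naive (14 adjusted over the list alone, camera adjusted p = 2.35e-08, adjusted p = 0.0495 with an estimated correlation), with Zeb2, which had 7 of its 8 Naive fragments in Naive replicate 1, at 12.42 ± 0.44, Tbx21 at 6.77 ± 0.25 and Prdm1 at 6.90 ± 0.37. Zeb2 stood at 14.37 without Naive replicate 1, which left 1 Naive fragment. Of 20 cytotoxic molecules 18 rose (19 adjusted over the list alone, camera adjusted p = 2.10e-10, adjusted p = 0.04998 with an estimated correlation), and 12 of 12 NK-type receptors rose (12 adjusted over the list alone, camera adjusted p = 1.57e-08, adjusted p = 0.0495 with an estimated correlation). The NK-type receptors include Klrg1, on which SLEC but not Naive cells were gated. Lymphoid homing genes were lower for 8 of 10 (8 adjusted over the list alone, camera adjusted p = 0.000277, adjusted p = 0.187 with an estimated correlation). Cell cycle genes rose for 17 of 20 on the S phase list and 19 of 20 on the G2/M list (17 and 19 adjusted over the lists alone, camera adjusted p = 5.46e-07 and 5.30e-10, adjusted p = 0.0539 and adjusted p = 0.203 with an estimated correlation). Interferon-stimulated genes gave 3 higher and 9 lower of 20 (3 and 11 adjusted over the list alone, camera adjusted p = 0.0535, or 0.0478, 0.0473 and 0.0495 without Naive replicate 1, Naive replicate 3 and SLEC replicate 2), with Oasl2 at -3.34 ± 0.23, Oas2 at -4.72 ± 0.43 and Oas1a at 1.79 ± 0.15. The receptor genes Il6ra and Il6st stood at -6.31 ± 0.30 and -4.37 ± 0.22, and Tox at -2.68 ± 0.22. Beside these, 12 of 13 B cell markers and 14 of 14 myeloid markers were higher in SLEC (12 and 14 adjusted over the lists alone, camera adjusted p = 2.90e-06 and 1.62e-07, adjusted p = 0.266 and adjusted p = 0.0584 with an estimated correlation), and Cd74 stood at 193 ± 12.5 FPKM against 6.34 ± 1.35. So were 4 of 4 plasma cell markers tested (4 adjusted over the list alone). Red cell and platelet markers were higher for 6 of 8 (6 adjusted over the list alone, camera adjusted p = 0.0171, adjusted p = 0.352 with an estimated correlation). Immediate early and stress genes gave 11 higher and 1 lower of 15 (13 and 1 adjusted over the list alone, camera adjusted p = 0.0121, adjusted p = 0.539 with an estimated correlation). In all, 3751 genes were higher and 2941 lower. No call among 55 genes examined ended when 1 library was left out.

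The comparison of Memory with Naive cells sets antigen-experienced cells of day 40 or later against cells from uninfected mice. Memory cells carried high levels of effector transcripts: Ccl5 stood at 7100 ± 910 FPKM (SD, n = 2) against 7.31 ± 0.53 in Naive (SD, n = 3), Gzmb was 193-fold higher, Gzmm 61.5-fold higher and Tbx21 43.7-fold higher. Il7r, on which Memory but not Naive cells were gated, was 2.66-fold and Bcl2 2.51-fold higher, both genes of T cell survival. Eomes, a T-box factor of memory cells, was 2.18-fold higher. Its list of 16 naive- and memory-associated factors gave 1 higher and 6 lower (1 and 6 adjusted over the list alone, camera adjusted p = 0.00365, adjusted p = 0.0651 with an estimated correlation). Tcf7 was 1.55-fold lower. The adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment ran from 1.08e-10 for Ccl5 to 0.00681 for Tcf7.

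Of 20 cytotoxic molecules 18 rose in Memory against Naive (20 adjusted over the list alone, camera adjusted p = 1.69e-16, adjusted p = 0.0488 with an estimated correlation). All 14 effector-associated factors rose (14 adjusted over the list alone, camera adjusted p = 6.93e-11, adjusted p = 0.0488 with an estimated correlation), among them Prdm1 and Bhlhe40. NK-type receptors were higher for 11 of 12 (12 adjusted over the list alone, camera adjusted p = 8.13e-12, adjusted p = 0.0488 with an estimated correlation), and inhibitory receptors and TOX gave 9 higher and 1 lower of 12 (9 and 1 adjusted over the list alone, camera adjusted p = 4.83e-06, adjusted p = 0.0495 with an estimated correlation), with Tigit at 6.29 ± 0.32, Lag3 at 5.85 ± 0.34 and Tox at -1.59 ± 0.24. Cytokine receptors gave 10 higher and 5 lower of 18 (10 and 7 adjusted over the list alone, camera adjusted p = 0.0817), with Il2rb, a subunit of the IL-2 and IL-15 receptors, at 2.19 ± 0.18. The higher members include Il7r, on which the Memory cells were gated. Chromatin modifiers gave 1 higher and 8 lower of 28 (1 and 10 adjusted over the list alone, camera adjusted p = 5.25e-05, adjusted p = 0.0584 with an estimated correlation), with Dnmt3a at -1.30 ± 0.15 and Tet3 at -0.91 ± 0.12. These 2 genes have 16642 and 16695 exonic bases, and fold changes of Memory against Naive fell with gene length (Spearman's rho -0.21). Interferon-stimulated genes gave 3 higher and 10 lower of 20 (3 and 12 adjusted over the list alone, camera adjusted p = 0.000477, adjusted p = 0.0584 with an estimated correlation). Beside these, 12 of 13 B cell markers were higher in Memory (12 adjusted over the list alone, camera adjusted p = 6.78e-08, adjusted p = 0.204 with an estimated correlation), with Cd74 at 70.3 ± 23.6 FPKM. So were 12 of 14 myeloid markers (12 adjusted over the list alone, camera adjusted p = 1.33e-07, adjusted p = 0.0584 with an estimated correlation) and 4 of 4 plasma cell markers tested (4 adjusted over the list alone). NK cell markers were higher for 4 of 6 (6 adjusted over the list alone, camera adjusted p = 8.36e-05, adjusted p = 0.0539 with an estimated correlation), a list that shares Klrb1c with the NK-type receptors. Of 15 immediate early and stress genes 4 were higher (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.215). Without Memory replicate 1 there were 10 higher (0.00748), and without Memory replicate 2 the calls were 2 lower, Egr1 and Egr2. Without Naive replicate 1 or 2 there were 2 higher, and without Naive replicate 3 there were 3 (0.0493). Without Memory replicate 2 the B cell markers gave 8 higher and 1 lower and the cytokine receptors 3 lower. Cytokine receptors gave 2, 3 and 3 lower without Naive replicate 1, 2 and 3. Itgae, which encodes CD103, stood at 64.1 ± 2.8 FPKM in Naive, at 0.416 in Memory replicate 1 and at 10.9 in Memory replicate 2. In all, 1729 genes were higher and 809 lower, with 482, 460 and 515 lower without Naive replicate 1, 2 and 3 and 1406 lower without Memory replicate 1. Of 56 genes examined, leaving out 1 library ended the calls of Dntt and Top2a: Dntt, at -4.18, was not called without Naive replicate 1 (-4.19), 2 (-4.18) or 3 (-4.15), and Top2a, at 0.69, was not called without Memory replicate 2 (0.65). Dntt stood at -3.14 without Memory replicate 1, which held 0 fragments of it.

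**Figure D4:**
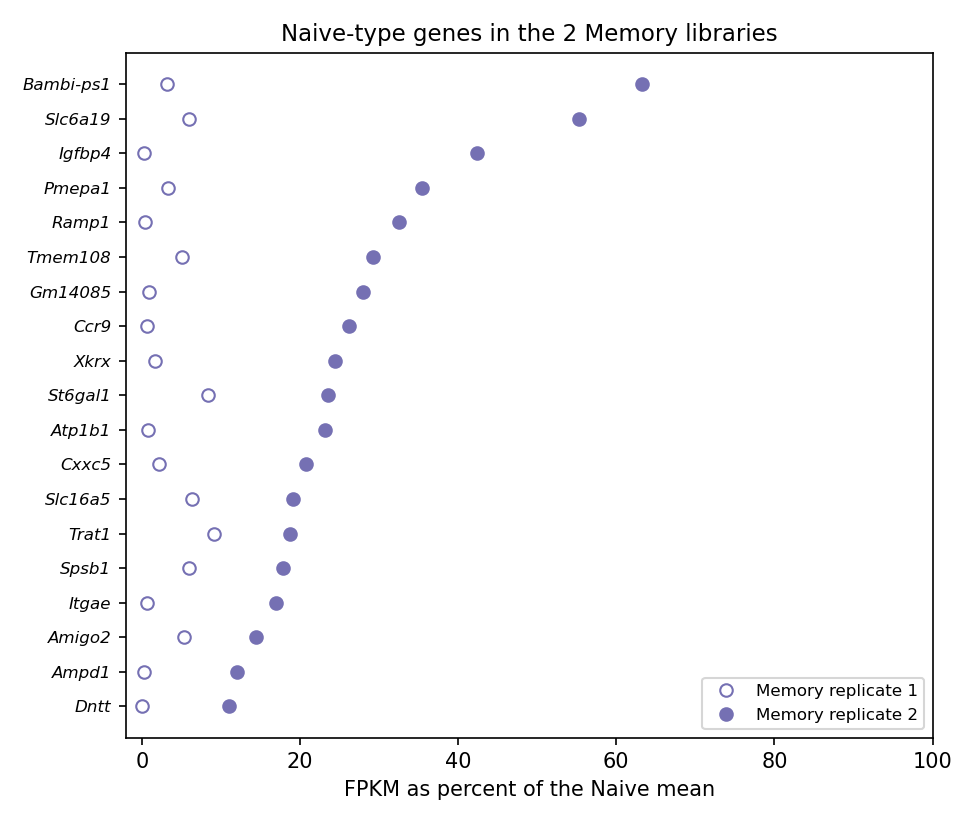
Level of 19 genes in Memory replicate 1 (open points) and Memory replicate 2 (filled points), in percent of the mean FPKM of the 3 Naive libraries; the genes stood at 5 FPKM or more in Naive and over 10-fold lower in each MPEC and SLEC library and in Memory replicate 1. All 19 stood higher in Memory replicate 2, from 11.1% to 63.2%.

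The comparison of Memory with SLEC sets the IL-7R high cells of day 40 or later against the KLRG1 high cells of day 9. Ccr7 was 39.0-fold higher in Memory (n = 2) than in SLEC (n = 3), or 21.1-fold without Memory replicate 2, Bcl2 6.11-fold higher and Tcf7 4.93-fold higher. Nsg2, a gene of vesicle trafficking in neurons, was 57.2-fold higher in Memory (adjusted p = 1.80e-08, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Gzma was 56.1-fold, Cx3cr1 13.2-fold, Gzmb 9.71-fold and Zeb2 9.71-fold lower in Memory. Gzma was 88.7-fold lower without Memory replicate 2 and Cx3cr1 20.1-fold lower without Memory replicate 1. Klrg1 and Il7r, set by the gates, stood at -4.32 ± 0.19 and 4.47 ± 0.28 on the log2 scale (SE). Nsg2 lies on chromosome 11, 32000463 to 32059202 (mm10, GENCODE).

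All 20 G2/M genes and 16 of 20 S phase genes were lower in Memory than in SLEC (20 and 19 adjusted over the lists alone, camera adjusted p = 4.41e-14 and 3.39e-09, adjusted p = 0.1496 and adjusted p = 0.0495 with an estimated correlation), Top2a at -3.19 ± 0.21. Of 20 cytotoxic molecules 2 were higher and 10 lower (4 and 12 adjusted over the list alone, camera adjusted p = 0.00817, adjusted p = 0.216 with an estimated correlation). Effector-associated factors were lower for 9 of 14 (10 adjusted over the list alone, camera adjusted p = 0.000130, adjusted p = 0.0584 with an estimated correlation), and naive- and memory-associated factors 9 higher and 1 lower of 16 (10 and 1 adjusted over the list alone, camera adjusted p = 0.00204, adjusted p = 0.0584 with an estimated correlation). Lymphoid homing genes were higher for 8 of 10 (9 adjusted over the list alone, camera adjusted p = 6.18e-05, adjusted p = 0.160 with an estimated correlation). Without Memory replicate 2 there were 5 (camera adjusted p = 0.00132): Ccr9, at 0.327 FPKM in Memory replicate 1 and 13.1 in Memory replicate 2, Itgae, at 0.416 and 10.9, and S1pr1 were not called. Naive- and memory-associated factors gave 7 higher there, and 9 higher and 3 lower without Memory replicate 1. Among inhibitory receptors and TOX, 4 were higher and 5 lower of 12 (5 and 5 adjusted over the list alone, camera adjusted p = 0.649), with Havcr2, which encodes TIM-3, at -4.36 ± 0.47 (-5.58 and -3.73 without Memory replicate 1 and 2) and Btla at 1.89 ± 0.27. Survival and apoptosis genes gave 1 higher and 6 lower of 16 (1 and 6 adjusted over the list alone, camera adjusted p = 0.0326, adjusted p = 0.1496 with an estimated correlation). Beside these, 6 of 13 B cell and 6 of 14 myeloid markers were lower in Memory (7 and 6 adjusted over the lists alone, camera adjusted p = 0.00176 and 0.00125, adjusted p = 0.438 and adjusted p = 0.171 with an estimated correlation), with Cd74 at -1.44 ± 0.22. Red cell and platelet markers were lower for 5 of 8 (5 adjusted over the list alone, camera adjusted p = 0.0105, adjusted p = 0.327 with an estimated correlation, and camera adjusted p = 0.0550 without Memory replicate 1). Immediate early and stress genes were lower for 5 of 15 (5 adjusted over the list alone, camera adjusted p = 0.0314, adjusted p = 0.605 with an estimated correlation). Without Memory replicate 2 these gave 9 lower and B cell markers 10 lower. Without Memory replicate 1 immediate early genes gave 2 higher and 3 lower (camera adjusted p = 0.655) and myeloid markers 11 lower, and B cell markers and survival genes did not pass camera (0.0926 and 0.108). Without SLEC replicate 3 immediate early genes gave 3 lower (0.0659). In all, 1754 genes were higher and 1684 lower. The count of 3438 was 2245 without SLEC replicate 1 and 2250 without SLEC replicate 2. Of 55 genes examined, leaving out 1 library ended the calls of Igfbp4, Prf1 and Tox. Without Memory replicate 2 Igfbp4 stood at 0.64 in place of 6.86 (7.84 without Memory replicate 1), Prf1 at -0.58 in place of -0.93 and Tox at 0.64 in place of 1.09, and Ifng passed at -1.63 in place of -0.98. Prf1 was not called without SLEC replicate 2 either (-0.81).

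Comparisons that share no library were set against each other across 13572 genes, as a description, since genes are not independent replicates. Fold changes of SLEC vs Naive and of Memory vs MPEC correlated at -0.51 (Pearson's r, Spearman's rho -0.49): of 1725 genes called in both, 1565 went in opposite directions, where independent lists would give 570. Those of MPEC vs Naive and of Memory vs SLEC correlated at -0.50 (rho -0.44), with 1940 of 2138 shared calls opposite, where independent lists would give 757. For example, Top2a rose in SLEC against Naive and fell in Memory against MPEC, and Tcf7 did the reverse. Fold changes of SLEC vs MPEC and of Memory vs Naive correlated at -0.07 (rho -0.07), with 500 of 869 shared calls in the same direction and 369 opposite, against 264 and 256 for independent lists. With at least 10 CPM required in 2 or more samples, this last correlation was 0.13 and turned its sign, and the others were -0.54 and -0.61.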

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

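The tests in this part were chosen only after the result was seen. In 51 genes in the MPEC libraries and 54 in the SLEC libraries the table carries the status HIDATA and a value of 0, against 17 in Naive and 1 in Memory. The comparisons in the report leave these genes out, and only a fit added after seeing the data keeps them. They drew attention because a status that stands for too much data was more frequent in the day 9 groups than in Naive. Of the 70 genes concerned, 50 carry the status in MPEC and SLEC, 16 in Naive alone, 3 in SLEC alone and 1, Eef1a1, in every group. By RefSeq, 50 of the 70 lie on chromosome 10, 15 on chromosome 11, 3 on chromosome 5, 1 on chromosome 7 and 1 on chromosome 9. Actb is listed at 0 in SLEC and stood at 3016 FPKM in Naive and 3874 in Memory. Eef2 is listed at 0 in SLEC and stood at 2409 FPKM in Naive, and Gpx4 is listed at 0 in MPEC and SLEC and stood at 157 FPKM in Naive.

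All 317 of 317 such values are exactly 0, which the status itself sets, so the zeros cannot show a loss of expression in the sorted cells. A candidate explanation is a fragment limit per locus in the authors' quantification, which would take the neighbours of a deeply covered gene with it. Of 70 placed genes, 65 lie within 100 kb of another gene with the status, while the highest of 1000 random draws gave 8. For these genes, this argues against a loss of expression gene by gene. Which gene filled each locus was not tested.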

How the results depend on the processing

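The fits named as added were chosen only after the result was seen, and the other alternatives were planned. Of 340 results for single genes, 299 were the same under every setting. Over 5087 values from settings, 4957 kept their side of the threshold, 17 of them with the other sign and called under neither fit, 117 no longer passed, 11 newly passed and 2 reversed. Both reversed in Memory vs MPEC without Memory replicate 2. Itgae went from 3.54 to -0.24, with a range of -0.24 to 4.50 when 1 library was left out, and Ccr9 went from 3.09, not called, to -1.29, called, with a range of -1.29 to 4.06. Memory replicate 2 held 10.9 FPKM of Itgae and Memory replicate 1 held 0.416.

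Counts of changed genes moved by over 1.5 times under these settings, and the cause was not tested. Settings that use fewer genes or samples are named as such. SLEC vs MPEC went from 2783 to 1700 with the replicate block and ranged from 1364 to 3181 when 1 library was left out. By less, SLEC vs Naive rose from 6692 to 8726 with only the groups compared, which also uses fewer samples. Memory vs MPEC went from 2305 to 1256 with the stricter count filter, which tests fewer genes, and to 1503 with limma on log2(FPKM + 0.1). It went to 494 with only the groups compared, which uses fewer samples and leaves out the smaller spread of Naive and SLEC. It ranged from 2038 to 3483 when 1 library was left out. MPEC vs Naive went from 5987 to 3802 with the stricter count filter. Memory vs SLEC went from 3438 and ranged from 2245 to 4088 when 1 library was left out. Requiring a log2 fold change of at least 1 left 1246 genes in SLEC vs MPEC, 1427 in Memory vs MPEC, 3426 in MPEC vs Naive, 3593 in SLEC vs Naive, 1622 in Memory vs Naive and 1702 in Memory vs SLEC. Of 144 list tests 85 passed, 11 with an estimated correlation, 86 with the replicate block and 80 to 87 when 1 library was left out. The correlation of SLEC vs MPEC with Memory vs Naive was 0.13 under the stricter count filter in place of -0.07, and that of MPEC vs Naive with Memory vs SLEC was -0.61 in place of -0.50. Residuals of same-numbered libraries correlated from -0.08 for SLEC and Memory replicate 2 to 0.23 for MPEC and SLEC replicate 1. Those of MPEC replicate 2 and SLEC replicate 3 correlated at 0.20. Whether libraries were paired cannot be settled this way, since the residuals of 2 libraries of 1 group mirror each other and the numbering was assumed. In fits added after seeing the data, SLEC vs MPEC gave 3948 with Memory replicate 2 left out of the fit. Where leaving out a library left 1 in a group, that library was assumed to vary like the other groups.

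For SLEC vs Naive, the labelled groups gave 6692 genes, and the highest of the other 9 splits gave 0. Each of these other splits put Naive and SLEC libraries in both of its groups. The difference between Naive and SLEC then counted as spread within groups, so low counts were largely set in advance. In those splits 9 to 58 genes had an unadjusted p under 0.05 in edgeR, and DESeq2 called 0 to 1. The count for the labelled groups was reached by 1 of 10 splits, and 10 are too few for a share under 0.05. Depth was lowest in Memory replicate 2, Naive replicate 3 and Memory replicate 1, at 28954673, 31096829 and 33538014 fragments, which limits what can be seen of genes with few fragments there. Fold changes against Naive fell with gene length across genes, with a Spearman's rho of -0.17 for MPEC, -0.15 for SLEC and -0.21 for Memory, and rho was 0.21 between the MPEC libraries. Whether length moved the chromatin modifiers, which had more lower than higher members against Naive, was not tested.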

Other observations

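The tests of explanations in this part were chosen only after the result was seen, while the gene lists were fixed before. Of 6 NK cell markers 5 were higher in SLEC than in Naive (5 adjusted over the list alone, camera adjusted p = 0.00373, adjusted p = 0.0754 with an estimated correlation). In SLEC against MPEC 2 were higher (2 adjusted over the list alone, camera adjusted p = 0.212). Klrb1c, which stands on the NK-type receptor list as well, rose by 10.02 ± 0.29 on the log2 scale (SE) in SLEC against Naive. Of 8 dendritic cell markers 6 were higher and 1 lower in MPEC than in Naive (6 and 1 adjusted over the list alone, camera adjusted p = 0.0110, adjusted p = 0.105 with an estimated correlation). These markers include Ccr9, also a lymphoid homing gene here, and Bst2, also an interferon-stimulated gene here. All 4 plasma cell markers tested were higher in MPEC than in Naive (4 adjusted over the list alone) and lower in SLEC than in MPEC (4 adjusted over the list alone), with Jchain at 46.4 ± 15.3 FPKM in MPEC (SD, n = 2) and 11.9 ± 3.5 in SLEC (SD, n = 3). Of 8 red cell and platelet markers tested 7 were higher in MPEC than in Naive (8 adjusted over the list alone, camera adjusted p = 0.00122, adjusted p = 0.217 with an estimated correlation). Among 6 CD4 T cell markers edgeR called 0 between SLEC and MPEC, with 2 at an unadjusted p under 0.05 and 1 call by DESeq2 (camera adjusted p = 0.648). Of 7 gate markers 3 were higher in Memory than in MPEC (4 adjusted over the list alone, camera adjusted p = 0.0226, adjusted p = 0.327 with an estimated correlation, and camera adjusted p = 0.0848 and 0.0916 without MPEC replicate 1 and Memory replicate 1). Of 4 Y-linked genes 0 had enough fragments to be tested.

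Of 39 tested markers of B cells, myeloid cells, plasma cells, and red cells and platelets, 38 were called higher in MPEC than in Naive. In the MPEC libraries Cd74 stood at 725 and 736 FPKM, Hbb-b1 at 790 and 784 and S100a8 at 120 and 112. For Memory vs MPEC the medians of the 4 lists lay 5.23 apart on the log2 scale. The 95th percentile over 10000 random exchanges of members between the lists was 3.29. The red cell and platelet list stood at -6.77 and the others from -2.80 to -1.53. This argues against 1 mix of other cells at a lower share in Memory only if T cells express none of these markers. For SLEC vs MPEC the medians lay 0.62 apart, between the 5th and 95th percentiles of 0.21 and 0.83, so 1 mix at a lower share cannot be told apart from lists that moved apart by less than this test can show. RNA of other cell types in the MPEC samples, as doublets or free RNA, is a candidate explanation. These counts cannot tell it apart from expression by the T cells themselves. The sort on CD8, CD44 and Thy1.1 would remove single cells of other types, but not free RNA or doublets that hold a T cell. Of the 39 markers, 11 stood at a mean of 1 FPKM or more in Naive cells, and 0 stand on another fixed list.

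Naive-type transcripts stood higher in Memory replicate 2 than in Memory replicate 1. Of 19 genes at 5 FPKM or more in Naive and over 10-fold lower in each MPEC and SLEC library and in Memory replicate 1, all stood at 11.1% or more of the Naive level in Memory replicate 2 (median 23.6%), while the same rule with the Memory replicates exchanged gave 0 genes. Naive cells in Memory replicate 2 may account for this, although the CD44 gate would remove them. The change between the Memory libraries fell with gene length (Spearman's rho -0.26 across genes), but a bias of the library towards short genes is argued against as the whole cause: the median change was 3.23 on the log2 scale for the 19 genes, picked for low values in Memory replicate 1, and 2.16 for 28 genes picked by the same rule without the Memory libraries, while the highest of 10000 sets matched on length and level gave 1.18 and 0.76. Over 108 genes at 5 FPKM or more in each MPEC and SLEC library and over 20-fold lower in each Naive library the median was 80.2% of the Memory replicate 1 level, with quartiles of 62.1% and 151%. Of these genes 66 stood lower in Memory replicate 2 and 42 higher. The quartiles give the spread between genes, not the uncertainty of the median. The FPKM of all genes summed to 699432 in Memory replicate 1 and 884630 in Memory replicate 2, and the values were not rescaled. Fewer antigen-experienced cells thus cannot be told apart from no change. A difference in time after day 40 or in the makeup of memory cells was not tested.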
